A study of Sinonovacula constricta with 9 samples.

How the data were processed

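RNA sequencing libraries, 9 in all, were analysed, 3 from each of 3 salinities (5, 15 and 25 psu), all from total RNA of whole juvenile Sinonovacula constricta after 6 h of exposure. Per the labels' protocols, RNA was extracted with Trizol and libraries were made with the NEBNext Ultra RNA kit for Illumina. That kit is not described there as keeping the strand, so overlapping transcripts of opposite strands cannot be told apart.

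The authors deposited 1 table per library with an estimated read count (expected count) and an FPKM value for each of 246672 unigenes, per the file headers. RSEM and Bowtie2 are named in the submitters' processing notes, without versions. The deposited counts are not whole for 25.0 to 27.6% of unigenes in a library, since reads that fit several unigenes were divided among them. The FPKM values were computed by the authors, per the file headers, and are rounded to 2 decimals. The assembler, the clustering tool and any filter on the assembly are not given in the sources used here. The identifiers fall into 59091 assembly clusters, and 1 of these holds 178061 unigenes (72.2%), so related transcripts, alleles and paralogs may share reads and the counts of single unigenes are uncertain to that extent. No table pairs the identifiers with gene names. The gene lists fixed before the data were examined (osmolyte metabolism and transport, ion transport, aquaporins, chaperones, antioxidants, apoptosis, immunity, central metabolism, ribosome, cilia, muscle, mantle, algal food) could therefore not be tested.

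The counts were rounded to whole numbers and unigenes were kept with edgeR's filterByExpr (count minimum 10, 3 groups), which left 71915 unigenes, holding 97.7 to 98.6% of the counts of each library. Libraries were scaled with TMM factors. The test was edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3, robust) in 1 model with the 3 groups and all 9 libraries, and p-values were adjusted with Benjamini-Hochberg at 0.05. The contrasts tested were 5 against 15 psu, 25 against 15 psu, 25 against 5 psu, and the mean of 5 and 25 psu against 15 psu. Standard errors of log2 fold changes are the fold change divided by the square root of its F statistic, and 95% intervals use the normal quantile. Both can be too small with 3 libraries per group and where a group holds few counts. CPM values use TMM-scaled library sizes. Abundance classes were set on the mean FPKM of all 9 libraries. Among unigenes with an adjusted p under 0.05, a mean of at least 10 FPKM and no overlap between the libraries of both groups, the 1 with the largest rise and the 1 with the largest fall in each comparison with 15 psu are named. This rule, the tests and the alternatives were set before the data were examined, except for the choices said to have been made later.

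Total counts ran from 15897903 to 18427234 per library. A count of 0 allows up to 3 counts, and this covers counting error only. On data simulated from the real means and dispersions of the 71915 unigenes, with 50 unigenes changed at each of 4 fold sizes, the test of 5 against 15 psu recovered 0% of the 1.5-fold, 20% of the 2-fold, 48% of the 4-fold and 64% of the 8-fold changes, with 4 of 70 calls on unchanged unigenes. For 25 against 15 psu these were 2%, 12%, 36% and 62%, with 3 of 59 calls on unchanged unigenes. DESeq2's Wald test made 72 of its 159 calls and 52 of its 140 calls on unchanged unigenes in the same data. The real libraries gave far more edgeR calls, 2053 and 1687, and the Benjamini-Hochberg cut is stricter where few unigenes change. The simulated shares may therefore not hold for the real lists.

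The labels give no sequencing batch or date. The titles give the 3 groups the same replicate numbers, but no label says that a number marks a shared batch, and the deviations of same-numbered libraries from their group means correlated at -0.017 to 0.106, over 0.1 in 1 of 9 pairs, so the numbers were not taken to pair the libraries. Replicates of a group differed by more than counting noise (chi-square per degree of freedom of 4.19 to 18.9), which does not tell separate cultures from repeat libraries of 1 pool of RNA. Under RSEM's definition an effective length is the unigene's length less a mean fragment length. Effective lengths implied by the deposited count and FPKM therefore gave each library an offset in nucleotides, over unigenes with a mean of at least 2000 counts. Alternatives were other scalings, DESeq2 (1.42.0), limma-voom (limma 3.58.1), limma on log2(FPKM + 1) and log2(FPKM + 0.1), other filters, thinning, a replicate block, sums per assembly cluster, leaving out each library, and, chosen after the data were seen, the length offset as a covariate.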

Results

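The razor clam Sinonovacula constricta is a bivalve mollusc that lives buried in estuarine mudflats, where the salinity of the water varies. Transcript levels were measured by RNA sequencing in whole juveniles on day 15 after fertilization, after 6 h at 5 psu (low salinity), 15 psu (the control, described as optimal) or 25 psu (high salinity). The practical salinity unit (psu) is roughly grams of salt per kilogram of water. Each group held 3 libraries, 9 in all, with total estimated counts from 15897903 to 18427234 per library. The transcript sequences listed under numbered cluster identifiers, called unigenes here, numbered 246672, of which 71915 had enough counts to be tested. No gene names came with the identifiers, so functions and genome positions are not given. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries.

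The libraries were ordered by salinity, with no overlap between groups, along the first principal component, which held 24.8% of the variance. Scores on that component ran from -127.8 to -97.4 at 5 psu, from -7.6 to 9.5 at 15 psu and from 108 to 112.1 at 25 psu. Pearson correlations across unigenes of log2 CPM (counts scaled to library size) were 0.898 to 0.903 between control libraries, 0.906 to 0.907 between libraries at 25 psu and 0.877 to 0.902 between libraries at 5 psu. Between groups they were 0.866 to 0.890 for 5 and 15 psu, which overlapped the range within 5 psu, 0.883 to 0.888 for 15 and 25 psu, and 0.845 to 0.864 for 5 and 25 psu. Replicate 3 at 5 psu correlated at 0.890 with control replicate 3 and at 0.877 with replicate 1 of its own group. On the second component, which held 13.6% of the variance, the 3 libraries at 5 psu were spread from -93.3 to 134.5.

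At a minimum of 1 count, fewer unigenes were detected in each library at 25 psu than in any at the other salinities. With at least 1 count after rounding, 147598 ± 3247 unigenes (SD, n = 3) were detected at 25 psu, 158257 ± 1555 (SD, n = 3) at 15 psu and 157449 ± 5020 (SD, n = 3) at 5 psu. After all libraries were thinned to the smallest total, the means were 146732 ± 2098, 155996 ± 349 and 155496 ± 3384 (SD, n = 3 each). All 3 libraries at 25 psu lay below the other 6, and the exact two-sided permutation p of 25 against 15 psu was 0.1, the smallest that 3 against 3 allows. At a minimum of 5 or 10 counts the libraries at 25 psu lay below those at 15 psu but overlapped those at 5 psu (exact two-sided permutation p = 0.2 for 25 against 5 psu at both minimums). Over the 3 groups the exact permutation p of the F statistic was 0.0286 after thinning. The 100 most abundant unigenes took 31.8% ± 3.87, 30.7% ± 1.36 and 29.6% ± 0.552 of the counts (SD, n = 3 each) at 5, 15 and 25 psu, with no difference detected (exact permutation p = 0.582 over the 3 groups).

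**Figure D1:**
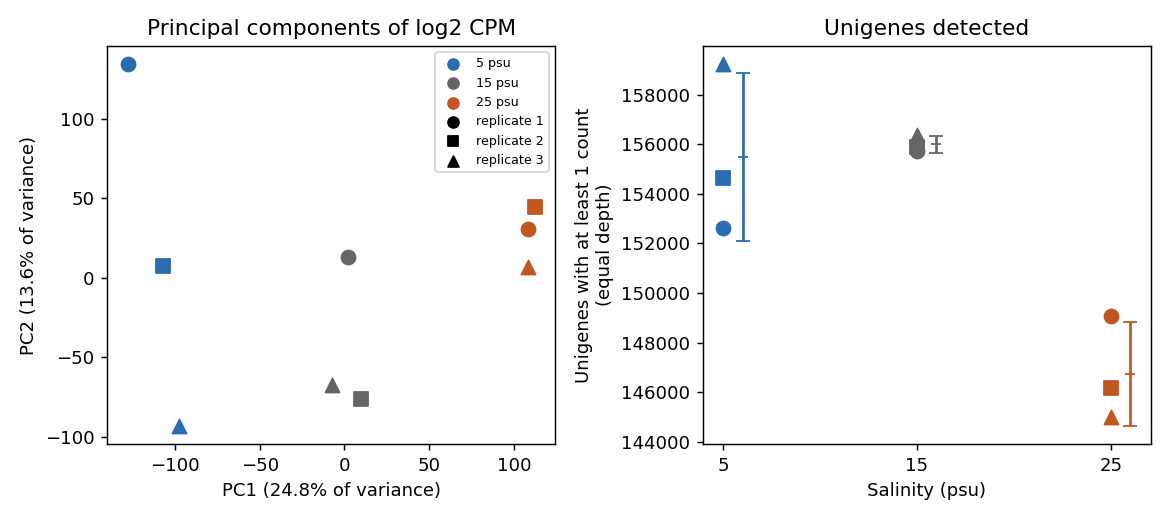
Left, scores of the 9 libraries on the first 2 principal components of log2 CPM, with colour for salinity and marker for replicate; the groups follow salinity along the first component. Right, unigenes with at least 1 count after thinning to equal depth, on an axis that does not start at 0, with the mean and SD of each group as bars; the 3 libraries at 25 psu lie below the other 6.

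The comparison of 5 with 15 psu asked which transcripts respond to an acute drop in salinity. Of the 71915 unigenes tested, 905 rose and 1148 fell at 5 psu (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), which is 2.85% of those tested. The 3 libraries of both groups did not overlap for any of these unigenes. Chance gives that separation in 10% of unselected unigenes, but these were chosen by a test on the same libraries, which favours it. The median change was 2.43-fold among those that rose and 1.95-fold among those that fell, and 240 rose by at least 4-fold while 86 fell by as much. These values are the same with unigenes at 0 in every library of a group (18 that rose and 21 that fell) set at a floor of 3 counts over the group. In the abundant classes falls outnumbered rises: in the class with a mean of 100 FPKM (fragments per kilobase of unigene, scaled to library size) and over, 80 fell and 35 rose of 943 tested, and in the class of 10 to 100 FPKM, 403 fell and 239 rose of 7851. In the class of 1 to 10 FPKM, 600 fell and 557 rose of 41802, a balance that turned with DESeq2 size factors (569 and 576) and more so with the libraries at 25 psu left out (239 and 386). Under 1 FPKM 65 fell and 74 rose of 21319, which turned with library totals alone (65 and 64) and widened with the libraries at 25 psu left out (35 and 69).

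Cluster-8005.9267 had the largest rise at 5 psu among unigenes of at least 10 FPKM whose libraries did not overlap. It was higher in 3 of 3 libraries and stood at 12.2 ± 3.45 CPM (SD, n = 3) at 5 psu and at 0.0774 ± 0.0916 CPM (SD, n = 3) at 15 psu, where the 3 libraries held 4 counts in all. Its log2 fold change was 7.17 (SE 0.51, likely too small at 4 control counts, edgeR adjusted p = 9.71e-05). It was 6.66, 6.97 and 8.41 without control replicates 1, 2 and 3. At 25 psu it stood at 0.085 ± 0.041 CPM (SD, n = 3), a log2 difference of 0.11 from the control with a 95% interval of -1.68 to 1.90. Cluster-8005.101936 had the largest fall among unigenes chosen by the same rule, and was lower in 3 of 3 libraries. It went from 1.96 ± 0.257 CPM (SD, n = 3) at 15 psu to 0.282 ± 0.214 CPM (SD, n = 3) at 5 psu. Its log2 fold change was -2.71 (SE 0.40, edgeR adjusted p = 0.00547), and -2.407, -2.475 and -3.548 without replicates 1, 2 and 3 at 5 psu. This unigene rose at 25 psu to 5.40 ± 0.718 CPM (SD, n = 3; log2 fold change 1.46, SE 0.32, edgeR adjusted p = 0.0482). Both are short by their implied effective lengths, 157 and 121 nucleotides, and neither call held under limma-voom (adjusted p = 0.171 and 0.0891), where the log2 fold changes were 7.23 and -2.75. Over the alternatives run on these unigenes the adjusted p ran from 5.2e-17 to 0.171 and from 5.42e-06 to 0.0891.

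The count at 5 psu fell to 1059, 1218 and 1249 calls without control replicates 2, 1 and 3, and to 1201 without replicate 2 at 5 psu. With the fragment length offset of each library as a covariate it was 1305, and the median log2 fold change of the calls was 1.08 before and after (median SE 0.16 and 0.18). DESeq2's Wald test called 3245, and limma on log2(FPKM + 1) without a filter 1165. The count was 1210, with 658 higher and 552 lower, when the libraries at 25 psu were left out of the fit, so rises outnumbered falls there over all classes, as they did among changes of at least 2-fold (582 and 548), while falls outnumbered rises in the classes of 10 FPKM and over, at 226 against 176 and 52 against 27.

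The comparison of 25 with 15 psu asked the same of an acute rise in salinity. At 25 psu, 1199 unigenes rose and 488 fell (edgeR adjusted p under 0.05), 2.35% of those tested, again with no overlap between the libraries of both groups for any of them. The median change was 1.90-fold among those that rose and 2.17-fold among those that fell. Rises outnumbered falls in the abundant classes, with 57 higher and 19 lower at 100 FPKM and over, 441 higher and 96 lower from 10 to 100 FPKM, and 650 higher and 275 lower from 1 to 10 FPKM. Under 1 FPKM the balance was the other way, with 51 higher and 98 lower. Each class had the same direction with DESeq2 size factors, with library totals alone and with the libraries at 5 psu left out, except under 1 FPKM in the last, where 102 were higher and 97 lower.

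Cluster-8005.119293 had the largest rise at 25 psu under the same rule, and it rose at 5 psu as well. It stood at 1.63 ± 1.13 CPM at 15 psu, 36.2 ± 9.59 CPM at 25 psu and 47.2 ± 4.91 CPM at 5 psu (SD, n = 3 each). Its log2 fold change was 4.45 at 25 psu (SE 0.46, edgeR adjusted p = 0.0028) and 4.83 at 5 psu (SE 0.47, edgeR adjusted p = 0.00125). With the fragment length offset as a covariate the change at 25 psu was 5.12 (adjusted p = 0.0487), and over the alternatives run on it the adjusted p ran from 1.2e-12 to 0.0487. The difference between 25 and 5 psu was -0.38 on the log2 scale, with a 95% interval of -1.09 to 0.33. Cluster-8005.132259 had the largest fall at 25 psu under the same rule and rose at 5 psu. It held 60.4 ± 17.5 CPM at 5 psu, 5.51 ± 2.72 CPM at 15 psu and 0.129 ± 0.223 CPM at 25 psu (SD, n = 3 each), where 1 library held 6 counts and the others 0. The log2 fold change was -5.37 at 25 psu (SE 0.79, edgeR adjusted p = 0.0133) and 3.45 at 5 psu (SE 0.45, edgeR adjusted p = 0.00528). Without replicate 3 at 25 psu, the library with the 6 counts, the fitted value was -9.53, which is no bound since the libraries left at 25 psu were all at 0. The call at 25 psu was lost without replicate 1 or 2 at that salinity (adjusted p = 0.0546 and 0.0572, log2 fold change -4.76 and -4.84), under limma-voom (-6.12, adjusted p = 0.5), without the filter on low counts (-5.34, adjusted p = 0.0833) and with the fragment length offset as a covariate (-5.65, adjusted p = 0.0902). Over the alternatives run on it the adjusted p ran from 1.17e-07 to 0.5.

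Leaving out any 1 of the 6 compared libraries lowered the count at 25 psu, to 892, 855 and 680 without control replicates 1, 2 and 3 and to 931, 746 and 856 without replicates 1, 2 and 3 at 25 psu. The count was 1957, 1323 and 2396 without replicates 1, 2 and 3 at 5 psu, which share the fit. With all libraries at 5 psu left out it was 2288. This lay above the 1210 at 5 psu without the libraries at 25 psu, so the order of the 2 counts turned. The libraries also differed in fragment length as the deposited values imply it: the mean offset in effective length at 25 psu differed by -10.05 nucleotides from 15 psu and by -6.96 from 5 psu (exact two-sided permutation p = 0.1 for each, the smallest possible), and with this offset as a covariate 157 unigenes were called at 25 against 15 psu. The median log2 fold change of the 1687 calls was 0.98 before and 0.99 with the covariate, and their median SE 0.16 and 0.23. DESeq2's Wald test called 2939, and limma on log2(FPKM + 1) without a filter 597.

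**Figure D2:**
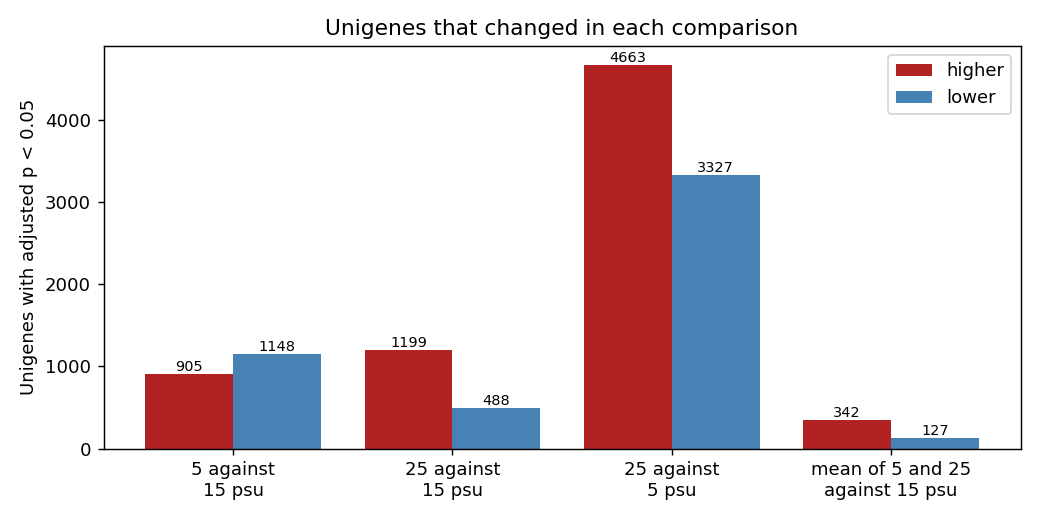
Number of unigenes with an adjusted p under 0.05 (edgeR quasi-likelihood test) in each comparison, higher in red and lower in blue, of 71915 tested. The difference between 25 and 5 psu has the most calls, 4663 higher and 3327 lower.

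The comparison of 25 with 5 psu tests the difference between the responses to high and to low salinity. Of the unigenes tested, 4663 were higher and 3327 lower at 25 psu than at 5 psu (edgeR adjusted p under 0.05), 11.1% of those tested. Among those that differed by at least 2-fold, the mean at 15 psu lay between the means at 5 and 25 psu for 2180 of the 2405 unigenes higher at 25 psu and for 1585 of the 1890 lower at 25 psu. On a log2 scale from 0 at 5 psu to 1 at 25 psu, the median position of the control was 0.55 (interquartile range 0.37 to 0.72) for the former and 0.49 (0.25 to 0.78) for the latter. Choosing unigenes by a large difference between 5 and 25 psu favours a control between them, and the share expected from that choice was not computed. Of the unigenes called here, 2900 higher and 2266 lower at 25 psu were called in neither comparison with 15 psu. The unigene with the smallest p fell with salinity, from 706.8 ± 31.6 CPM at 5 psu to 168 ± 2.98 CPM at 15 psu and 32.5 ± 0.461 CPM at 25 psu (SD, n = 3 each). It was singled out after its values were seen; its log2 fold changes were 2.07 (SE 0.07) at 5 psu and -2.37 (SE 0.07) at 25 psu against the control (edgeR adjusted p = 2.44e-06 and 8.76e-07). The count of 7990 fell to 5157 without replicate 2 at 5 psu, to 5064, 4934 and 5245 without replicates 1, 2 and 3 at 25 psu, and to 3658 with the fragment length offset as a covariate, where the median log2 fold change of the calls was 1.06 before and after and their median SE 0.20 and 0.24. Limma on log2(FPKM + 1) without a filter called 4176.

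**Figure D3:**
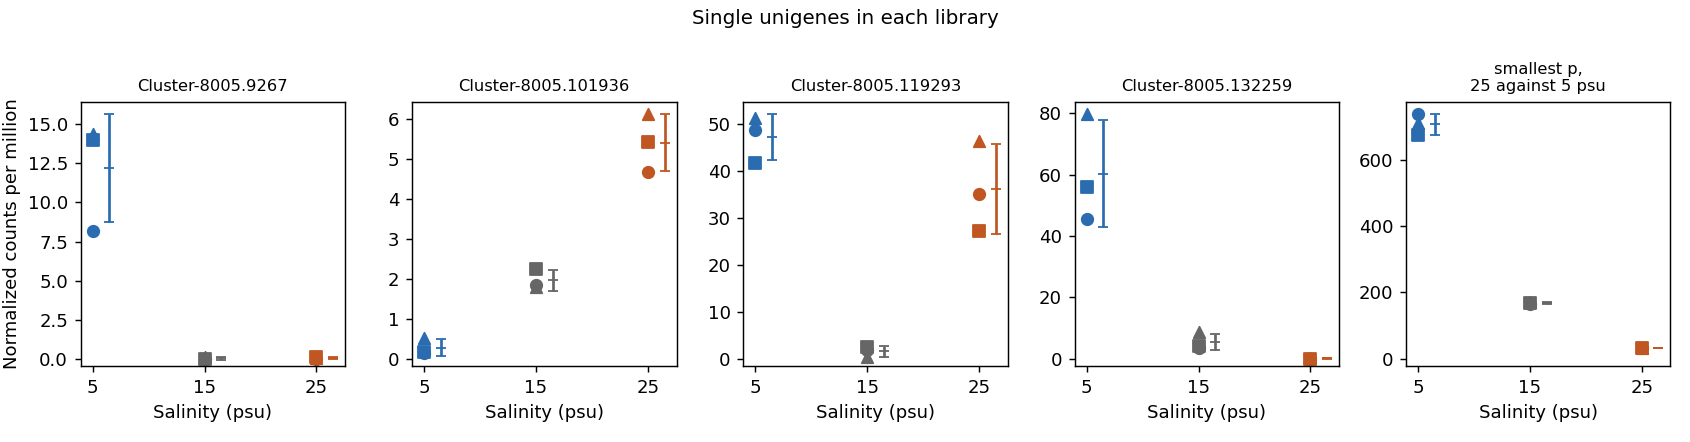
Normalized CPM of 5 unigenes in each library against salinity in psu; colour marks salinity, marker shape the replicate, and the offset bars the mean and SD of 3 libraries. Cluster-8005.119293 is higher at both 5 and 25 psu than at 15 psu, while Cluster-8005.132259 and the unigene with the smallest p at 25 against 5 psu fall from 5 to 25 psu.

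More unigenes were called in opposite directions at the 2 salinities than in the same direction. Against 15 psu, 266 unigenes fell at 5 psu and rose at 25 psu, and 48 rose at 5 psu and fell at 25 psu. Independent lists of these sizes would share 19.1 and 6.14 unigenes if all unigenes were equally likely to be called. The share called rose with abundance, from 0.652% under 1 FPKM to 12.2% at 100 FPKM and over at 5 psu. At 25 psu it rose from 0.699% to 8.06%, so numbers for independent lists are likely too low. In the same direction, 112 rose and 22 fell at both salinities, where independent lists would share 15.1 and 7.79. Across the tested unigenes, which are not independent replicates, the log2 fold changes at 5 and 25 psu had a Pearson r of 0.23 and a covariance of 0.149. In 20 simulations of unchanged groups that shared their 3 controls, r averaged 0.495 and the covariance 0.21 (0.201 to 0.217). No unigene was called in both comparisons there, but at most 1 was called in either, so that gives no value for shared calls. The observed covariance differed from the simulated mean by -0.0609. Both comparisons use the same 3 control libraries, too few to give each comparison controls of its own. The 314 opposite calls became 151, 145 and 118 without control replicates 1, 2 and 3, 201 without replicate 2 at 5 psu, 185, 146 and 166 without replicates 1, 2 and 3 at 25 psu, and 40 with the fragment length offset as a covariate. The 134 calls in the same direction became 85 without replicate 2 at 5 psu, 82 and 88 without replicates 2 and 3 at 25 psu, and 30 with that covariate.

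**Figure D4:**
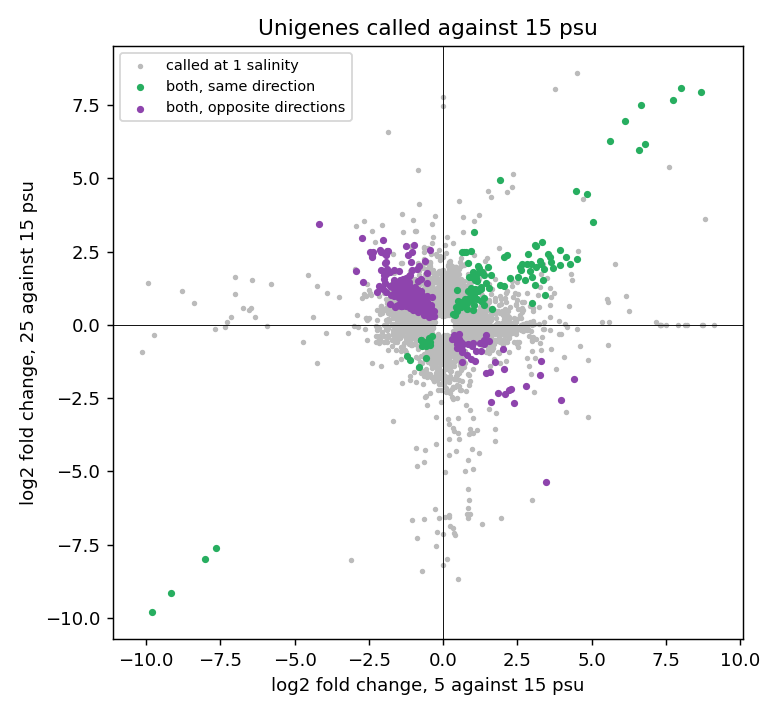
log2 fold change at 25 psu against that at 5 psu, both relative to 15 psu, for unigenes called in at least 1 of these comparisons. Purple points, 314, were called in opposite directions and green points, 134, in the same direction; grey points were called at 1 salinity.

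The contrast of the mean of 5 and 25 psu with 15 psu asked which unigenes moved away from the control on average over both stresses. Of those tested, 342 rose and 127 fell (edgeR adjusted p under 0.05). The 3 control libraries did not overlap the other 6 for 208 of the 342 and 74 of the 127. Chance gives that separation in 2.38% of unselected unigenes, but these were chosen by this contrast, which favours it. Of the 342, 108 were also called higher at each salinity by itself, and the median log2 fold change was 1.09 at 5 psu and 0.94 at 25 psu. Of the 127, 22 were called lower at each salinity, with medians of -0.77 and -0.50. Between 5 and 25 psu, 253 of the 342 and 84 of the 127 differed. The fold changes at 5 and 25 psu had opposite signs for 73 of the 342 and 26 of the 127. The count fell to 155, 140 and 134 without control replicates 1, 2 and 3, to 210 without replicate 2 at 5 psu, and to 277, 220 and 218 without replicates 1, 2 and 3 at 25 psu. With the fragment length offset as a covariate it was 81, and the median log2 fold change of the calls was 0.89 before and 0.92 after (median SE 0.13 and 0.16). It was 258 with a replicate block and 272 with limma on log2(FPKM + 1) without a filter, and it rose to 799 without a filter on low counts, 729 with a stricter filter and 1279 with DESeq2's Wald test.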

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

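Thinning for the detected unigenes was planned, while its reading as a test of depth was written after the result was seen. A first bound for variant contigs was written before its result, and the bound used here after it. The tests of shared controls, of abundant unigenes in detection, of mislabelling and of another organism were chosen only after the result was seen. So were the fragment length covariate and the definition of unigenes private to 1 library.

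Among unigenes outside the tested set, control replicate 2 held many that the other libraries lacked. With at least 30 counts and at least 90% of all their counts in 1 library, 657 unigenes were private to it, with 104094 counts (0.565% of that library), against 5 to 16 private unigenes in each of the other 8 libraries. After thinning, 571 of these 657 remained private, against at most 13 private unigenes elsewhere, which argues against depth. The tested unigenes hold none of the set, so the correlations given above already leave it out. There the lowest correlation of the library with its own group exceeded the highest with another group by 0.0096, which argues against a wrong label. Variant contigs of the same transcripts were first tested by the number of unigenes lost in that library alone, 311, which met a bound written beforehand (a share of 10% of the private ones) and so spoke for them. Every library lost 311 to 517, so that bound could not tell libraries apart, and after this was seen it was replaced by the difference from the median of the other libraries, -91 (SD 69.0). The library nearest in depth lost 311 as well, a difference of 0 that lies within that SD of the bound, so variant contigs stay open too. Reads from another organism or tissue may be the source and stay open for want of sequences to match. That 97.7% of the set had 0 counts in the other 8 libraries does not speak for them, since the definition asks for few counts elsewhere and the private sets of the other libraries had 70 to 100%. Outside that definition the set also stood apart, with 273 of the 657 in the largest assembly cluster, against 7 of 10 in the lowest and all in most of the other private sets, and a median effective length of 851 nucleotides against 1386 to 2779, which names no source. No biological explanation was tested, since the design names no difference between control libraries.

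More unigenes were called in opposite directions at 5 and 25 psu, 314, than in the same direction. Shared control libraries push fold changes towards the same direction, with a mean covariance of 0.21 in the simulations of unchanged groups against 0.149 observed. Those simulations made at most 1 call in a comparison, so their lack of calls in both comparisons cannot weigh shared controls. With DESeq2 size factors or library totals at least 259 opposite calls were made, against 21.7 for independent lists. Numbers for independent lists take all unigenes as equally likely to be called, and are likely too low since abundant ones were called more often. With the fragment length offset as a covariate 40 opposite calls were made, 39 of them among the 314, against 1.50 for independent lists. All 314 had opposite signs with it. At 25 psu their median log2 fold change was 0.84 (median SE 0.13) before and 0.88 (median SE 0.19) after. The median fold thus did not shrink while the errors grew, the offset being partly collinear with the groups. The Benjamini-Hochberg cut was also stricter, with 157 calls at 25 against 15 psu in place of 1687. How much each added to the lost calls was not tested. That transcript levels may follow salinity in steps stays a hypothesis, and differences between cultures, which the labels do not describe, stay open.

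Fewer unigenes were detected at 25 psu at a minimum of 1 count. The separation from 5 psu was lost at 5 and at 10 counts. Those minimums were not applied after thinning, so depth may account for that loss. After thinning, the lowest of the other 6 libraries exceeded the highest at 25 psu by 3566 unigenes, which argues against depth, and by 5973 without the 100 most abundant unigenes, which argues against a few unigenes taking the counts. The difference of 25 from 15 psu was -9264 after thinning, and -8191 (SE 2836) with the fragment length offset as a covariate. The offsets at 25 psu, 0 to 1.90 nucleotides, lay below those of the other 6 libraries. The fit thus takes its slope mostly from those 6 and cannot tell how much the offset accounts for. Salinity, and differences in RNA or library preparation that run with the groups, may each account for the lower number and were not tested.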

How the results depend on the processing

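The covariate for fragment length and the thinning without the 100 most abundant unigenes were chosen after seeing the data, as were thinning, the covariate and both FPKM fits for the named unigenes. In the order 5 against 15 psu, 25 against 15 psu, 25 against 5 psu and the mean of both against 15 psu, the main counts were 2053, 1687, 7990 and 469. DESeq2's Wald test gave 3245, 2939 and 1279 for the first, the second and the mean contrast. In simulated data with few changed unigenes it made 72 of 159 and 52 of 140 calls on unchanged unigenes. An adjusted p under 0.01 gave 924, 584, 3462 and 139, and a change of at least 2-fold 1130, 817, 4295 and 212. Limma on log2(FPKM + 1) with no filter gave 1165, 597, 4176 and 272, over 227401 unigenes. Sums per assembly cluster gave 9, 2, 102 and 0 over 2597 clusters, since 1 cluster holds most unigenes. The covariate gave 1305, 157, 3658 and 81, of which 1280, 150, 3543 and 80 were among the main calls, with median folds nearly unmoved and larger errors in each. Leaving out the third group gave 1210 at 5 against 15 psu, 2288 at 25 against 15 psu and 5787 at 25 against 5 psu. That turned the order of the counts at 5 and 25 psu. For the mean contrast, no filter gave 799, a stricter filter 729 and the replicate block 258; the cause was not tested for these. The block moved the other counts by less than 1.5 times, to 1623, 1249 and 6981.

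Without 1 library each, the counts ranged from 1059 to 2262, from 680 to 2396, from 4934 to 7409 and from 134 to 652. The unigenes called at both salinities in the same direction (134) ranged from 82 to 177, and those in opposite directions (314) from 118 to 392. These were 257 and 562 with DESeq2 and 30 and 40 with the covariate. The difference in detected unigenes between 25 and 15 psu (-10659) was -6739 at a minimum of 5 counts and -4445 at 10. In the top quartile of abundance, 41.4% of calls were higher at 5 against 15 psu and 63.7% at 25 against 5 psu, against 30.4% and 70.1% at 100 FPKM and over. Rises outnumbered falls at 5 psu with the third group left out and among changes of at least 2-fold. The difference of 5 from 15 psu changed sign for detected unigenes (-807.7 in all libraries, 1325 without replicate 1 at 5 psu and 89.8 without control replicate 2) and for the share of the 100 most abundant (1.05 and -0.841 without replicate 1 at 5 psu), neither of which passed a test. Library totals and DESeq2 size factors moved the median of all unigenes by less than 0.1 on the log2 scale. The 4 named unigenes kept their direction under the alternatives run on them, and with a pseudocount of 1 FPKM the log2 fold changes of Cluster-8005.9267, Cluster-8005.119293 and Cluster-8005.132259 shrank to 5.70, 3.396 and -1.999. The preset gene lists were not run for want of names, and leaving out the third group has no meaning for the mean contrast. Of simulated 2-fold changes, edgeR recovered 20% at 5 psu and 12% at 25 psu, in data with few changed unigenes. Neither depth nor the number of libraries was varied there, so neither can be named as the limit.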

Other observations

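The absence counts, the share of the second most abundant unigene, the assembly cluster values and the lengths were chosen after the data were seen. The unigenes missing at 25 psu had low counts elsewhere. In all 3 libraries at 25 psu, 625 unigenes had 0 counts while all 6 other libraries held at least 1, with a median of 2.67 counts per library in those 6. The corresponding numbers were 261 for 5 psu and 183 for 15 psu. Of the 84 ways to choose 3 of the 9 libraries, the libraries at 25 psu gave the highest number, with at most 345 for any choice that mixed salinities and a median of 177. In the other direction, 487 unigenes were present in every library at 5 psu and absent from the other 6, against 345 for 15 psu and 171 for 25 psu.

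The second most abundant unigene took 4.74% ± 1.36 of the counts at 5 psu, 2.64% ± 0.699 at 15 psu and 2.39% ± 0.240 at 25 psu (SD, n = 3 each). All 3 libraries at 5 psu lay above all 3 at 25 psu (exact two-sided permutation p = 0.1, the smallest possible), while 1 library at 5 psu, at 3.35%, lay below 1 control library, at 3.41%.

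Of the 2405 tested unigenes outside the largest assembly cluster, 0.998% changed at 5 psu and 0.249% at 25 psu against the control, and of the 69510 within it 2.92% and 2.42%. At 25 against 15 psu the median implied effective lengths were 1993 nucleotides for those that rose, 1773 for those that fell and 1305 for those not called. At 5 against 15 psu they were 1839, 1592 and 1306. Whether differences in counts, which make a change easier to call, account for the cluster and length differences was not tested.

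Other groupings of the libraries were fitted in the same way. For 5 against 15 psu, 1 of the 10 splits of the 6 libraries, the real one, gave 2053 calls, and the highest of the others gave 2. For 25 against 15 psu, 1 of 10 splits gave 1687 calls, with 2 as the highest other, and for 25 against 5 psu 1 of 10 gave 7990, with 1 as the highest other. These 10 splits are too few for a share under 0.05. For the mean of 5 and 25 psu against 15 psu, 40 splits were fitted, the real one and others drawn at random. Only the real one gave 469 calls, and the highest of the others gave 1. Chance can be excluded there only as the absence of any difference among the 3 groups, since the other splits mix 5 and 25 psu, whose differences widen the spread within groups.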
